A study of Mus musculus with 6 samples.

How the data were processed

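RNA was measured in liver sinusoidal endothelial cells (LSECs), the fenestrated cells lining the blood spaces between plates of hepatocytes. The cells came from mice of 2 genotypes, Tgfbr2f/f and an endothelial knockout of Tgfbr2 labelled ECKO. Both groups had received carbon tetrachloride (CCl4), a hepatotoxin used to produce liver fibrosis, by intraperitoneal injection 2 times per week over 6 weeks, per the labels' protocols. Each genotype had 3 libraries, numbered 1 to 3 in the titles. How the LSECs were isolated is not given in the sources used here.

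Per the labels' protocols, total RNA was checked for integrity, purified, treated with DNase and separated into mRNA before fragmentation and cDNA synthesis. The submitters' processing notes name HISAT2 2.0.4, an aligner, and StringTie 1.3.0, a transcript assembler, with no role for either, and the builds mm10 and GRCm38.p4. The counter, annotation release, strand setting and filters are not given in the sources used here. Without a stated strand setting, reads from overlapping or antisense genes cannot be assigned with certainty, and members of families with near-identical copies, such as the major urinary protein (Mup) genes, can share reads.

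The deposited table holds raw counts per gene in 1 column per library, whole numbers with no scaling, per the file headers. It also holds FPKM columns (fragments scaled by gene length and library total) made by the authors, per the file headers. Those FPKM values equalled the count divided by gene length and by the library's total count to within a relative difference of 4.72e-06, for genes with over 200 counts in both libraries compared. No pooled columns were used, and 0 columns of per-sample values were left out. Of the gene identifiers in the table, 34267 (98.6%) matched a reference table of identifiers and symbols. The symbols and coordinates given here are those of the deposited table, on mm10/GRCm38.

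The table lists 34745 genes, of which 14663 had 0 counts in all 6 libraries. Library totals ranged from 17171850 to 25062755 counts. A count of 0 in a single library allows up to 3 counts, which is 0.124 to 0.200 CPM (the count scaled to library size) depending on the library. Such floors and the 95% counting intervals given for genes with 1 to 3 counts in a group (exact, from the conditional binomial) cover counting error only, since no molecular identifiers are described.

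Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13692, and libraries were scaled by TMM. ECKO was compared with Tgfbr2f/f by edgeR's quasi-likelihood F-test with robust dispersion, genotype as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are log2 of ECKO over Tgfbr2f/f, and CPM values are TMM-scaled means with SD. Standard errors (SE) were taken as the absolute log2 fold change divided by the square root of F. The design of the test, 31 gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

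The 31 lists (785 entries, 1 of them, Ahsp, not analysed here) cover components of TGF-beta and BMP signalling, TGF-beta induced genes, BMP-SMAD targets, extracellular matrix, sinusoidal identity, capillarization, endothelial-to-mesenchymal transition, angiocrine factors, Notch signalling, adhesion and chemokines, interferon response, antigen presentation, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, lipid metabolism and endocytosis. They also cover markers of hepatocytes, stellate cells, Kupffer cells, monocytes, neutrophils, T and NK cells, B and plasma cells, dendritic cells, cholangiocytes, erythroid cells and platelets, and mesothelium with lymphatic endothelium. Immediate early, mitochondrial genome and cytosolic ribosomal protein genes were listed as signs of handling and RNA quality. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. The test was repeated with a correlation estimated for each list, and with fry, which asks whether a list's genes move on balance one way.

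Named genes were Tgfbr2, the 12 genes with the largest absolute log2 fold change in each direction, and up to 4 tested members of each list with the smallest p. The 12 genes per direction had to pass the threshold, separate all libraries of the groups, average at least 1 CPM and carry an established symbol. That rule gave 136 genes, 79 of which passed the threshold. Rab22a, P4ha2 and Pecam1 fall outside the rule and were chosen after their values were seen. The same holds for genes named below only as members of the lists on protein folding and stress in the endoplasmic reticulum, clock genes and sex-biased liver genes. Some members of those lists, such as Mup14, Selenbp2 and Xbp1, were named by the rule. The plotted genes were picked from the named genes and Rab22a after their values were seen.

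Alternatives were median-ratio size factors from DESeq2 1.42.0 in the edgeR fit, total count scaling, the DESeq2 Wald test, limma-voom, no filter on low counts, a mean of at least 1 CPM, quantile normalization for the lists, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were limma-trend on log2(FPKM + 1) with a mean FPKM of at least 1, leaving out all genes of the mitochondrial chromosome, leaving out the genes of the other-cell-type lists, and, for the lists, total count scaling, the mean of at least 1 CPM and the estimated correlation together with the block or without f/f replicate 1. Principal components used the 500 most variable tested genes on log2 CPM.

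The steps were tested on simulated data, 10 draws of counts for these 6 libraries over 13518 to 13572 tested genes, with 200 genes changed. Where each gene kept its own dispersion, the edgeR test recovered 12.0% of genes changed 1.5-fold, 55.8% of those changed 2-fold and 89.5% of those changed 4-fold, and 10.8% of its calls were unchanged genes. Where dispersion followed the trend, these were 17.4%, 68.7%, 95.6% and 5.23%. In the draws with each gene's own dispersion DESeq2 recovered 24.6%, 69.1% and 92.1%, with 23.8% of its calls unchanged genes. In draws over 13530 to 13574 genes, camera called 20 of 20 lists of 30 genes shifted by 0.5 on the log2 scale and 2 of 180 unshifted lists. Genes were drawn independently of each other, so these draws do not show how often camera calls unshifted lists of correlated genes. In the real data the estimated correlation was 0.275 for the matrix list and 0.704 for the cell cycle list. Replicates within each group differed by more than sampling noise (chi-square per degree of freedom 30.8 to 121), so none was treated as a copy of another. That test does not show that the libraries came from separate mice.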

Results

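Gene expression was profiled by mRNA sequencing in LSECs from Tgfbr2f/f (f/f) mice and from mice labelled ECKO. That label denotes an endothelial knockout of Tgfbr2, which encodes the type II receptor for TGF-beta. All mice had received CCl4 for 6 weeks, and each genotype had 3 libraries. Total counts were 25062755, 17632271 and 20825775 in the f/f libraries and 18035620, 17171850 and 18671217 in the libraries labelled ECKO. The labels do not state that each library came from a separate mouse, so the p-values measure the spread between these samples. For any single value compared alone, 3 libraries against 3 cannot give an exact permutation p below 0.1. The comparison addresses how gene expression in LSECs after CCl4 differs between f/f mice and mice labelled as an endothelial knockout of Tgfbr2. TGF-beta signalling itself was not measured.

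Tgfbr2 (ENSMUSG00000032440, chromosome 9, 116087698 to 116175363 on mm10/GRCm38, minus strand) was not lower in the libraries labelled ECKO. Its level was 427 ± 35.1 CPM in f/f and 499 ± 12.1 CPM in the libraries labelled ECKO (mean ± SD, n = 3 each), a log2 fold change of 0.22 (SE 0.10; edgeR quasi-likelihood adjusted p = 0.228). The f/f libraries held 387, 442 and 452 CPM (9255, 9000 and 10914 counts), and the libraries labelled ECKO held 498, 487 and 511 CPM (7475, 8386 and 8917 counts). Under total count scaling the log2 fold change was -0.02 (adjusted p = 0.953), and on FPKM it was -0.01 (adjusted p = 0.983). The labels do not state which part of the gene is deleted, and a transcript lacking that part would still be counted, so gene-level counts cannot check the deletion. Every direction below is that of the libraries labelled ECKO.

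In those libraries 382 of 13692 tested genes were lower and 170 higher. The falls included 23 of 55 matrix genes and 12 of 30 stellate cell markers, lists that camera called lower with a preset correlation between genes but not with an estimated one (adjusted p = 0.406 for both). Col6a1, a chain of type VI collagen, fell from 101 ± 20.7 to 21.7 ± 0.149 CPM (n = 3 each), a log2 fold change of -2.22 (SE 0.16; adjusted p = 0.00313). Thbs1, which encodes the TGF-beta activating matrix protein thrombospondin 1, fell from 48.8 ± 10.6 to 6.64 ± 2.02 CPM, a log2 fold change of -2.87 (SE 0.27; adjusted p = 0.00853). Tcf21, a transcription factor of stellate cells, fell from 35.9 ± 1.18 to 8.75 ± 2.34 CPM (log2 fold change -2.04, SE 0.20, adjusted p = 0.00853). Selenbp2, a male-biased hepatocyte gene, rose from 4.50 ± 1.52 to 94.8 ± 33.7 CPM (log2 fold change 4.39, SE 0.35, adjusted p = 0.00853). These 4 genes passed without each library in turn, and their values in each library are plotted beside those of other genes.

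**Figure D1:**
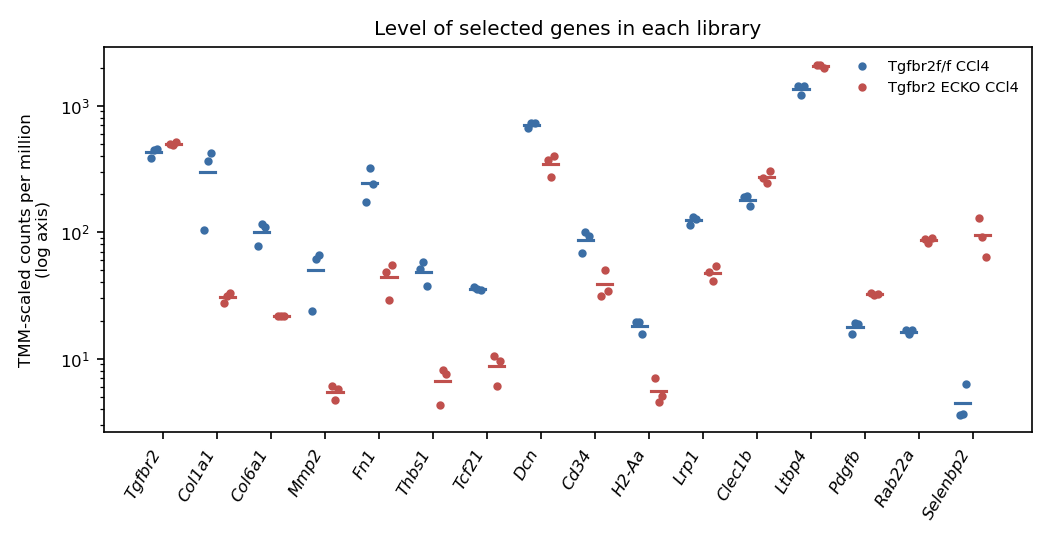
Level of 16 genes in each library, as TMM-scaled CPM on a log axis; points are the 3 libraries of each genotype and the bar is their mean. Tgfbr2 lies between 387 and 511 CPM in the 6 libraries. The 3 libraries labelled ECKO lie below the 3 f/f libraries for Col1a1, Col6a1, Mmp2, Fn1, Thbs1, Tcf21, Dcn, Cd34, H2-Aa and Lrp1, and above them for Tgfbr2, Clec1b, Ltbp4, Pdgfb, Rab22a and Selenbp2.

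Of 13692 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 170 were higher and 382 lower in the libraries labelled ECKO, and 51 and 291 of these changed by at least 1 on the log2 scale. All 552 separated the 3 libraries of each group. Among all genes 4227 (30.9%) did so, against 10% by chance. Falls made up 69.2% of the calls. Total count scaling, under which the median of all genes was -0.22 against 0.01 in the main test, called 63 higher and 1209 lower, and the FPKM test, with a median of -0.15 over 10464 genes, called 28 and 379 (93.1% lower). The total varied with single libraries, being 1012 without f/f replicate 1, 246 without f/f replicate 2, 91 without f/f replicate 3, 35 without ECKO replicate 1, 193 without ECKO replicate 2 and 109 without ECKO replicate 3. These kept 481, 194, 82, 33, 169 and 103 of the 552 calls, and none reversed. The first principal component (60.5% of variance) placed the f/f libraries at -14.7, -30.4 and -24.8 and the libraries labelled ECKO at 26.1, 21.3 and 22.5. Pearson correlations between libraries, over genes within each pair, were 0.965 to 0.984 within groups and 0.947 to 0.966 between them. The f/f library nearest the other group was replicate 1. Its correlation was 0.9663 with ECKO replicate 3, against 0.9654 and 0.9764 with f/f replicates 2 and 3. Its mitochondrial share, 23.5%, lay within the 19.7% to 32.4% of the libraries labelled ECKO. Whether this underlies the 1012 calls without it was not tested.

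**Figure D2:**
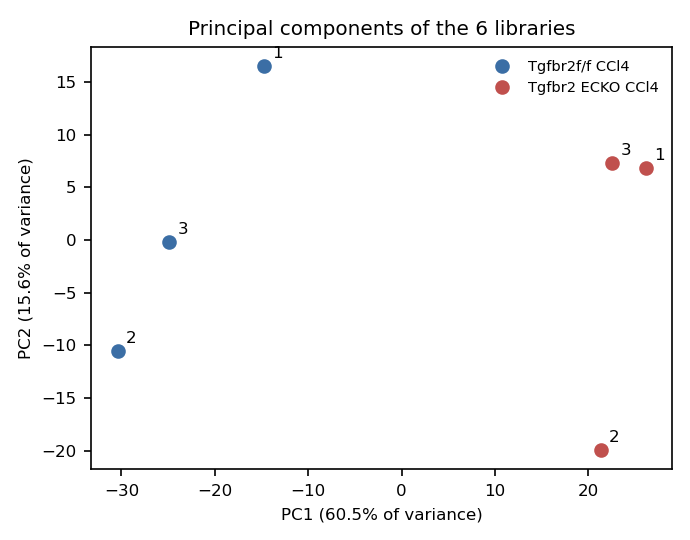
Scores of the 6 libraries on the first and second principal components of log2 CPM of the 500 most variable tested genes, coloured by genotype and numbered by replicate. The first component (60.5% of variance) separates f/f at -30.4 to -14.7 from the libraries labelled ECKO at 21.3 to 26.1, and the second (15.6%) spreads libraries within each group.

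Transcripts of the mitochondrial genome took 23.5%, 14.2% and 11.5% of counts in f/f (16.4 ± 6.33) and 32.4%, 19.7% and 23.7% in the libraries labelled ECKO (25.3 ± 6.47; exact permutation p = 0.2, two-sided). On average 17604 genes were detected in f/f libraries and 16482 in the libraries labelled ECKO. The 13 mitochondrial genes tested had a median log2 fold change of 0.91 and a camera call upward (adjusted p = 1.01e-04; adjusted p = 0.539 with an estimated correlation), which was lost under quantile normalization (adjusted p = 0.0854). Without f/f replicate 1 that median was 1.42. None passed on its own, over all genes or adjusted over the list alone. mt-Atp6, for example, went from 2091 ± 934 to 4305 ± 1238 CPM (adjusted p = 0.133). At an unadjusted p under 0.05 edgeR held 7 of the 13, DESeq2 called 3 higher after adjustment and limma-voom 0.

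Among 55 matrix and fibrosis genes, 23 fell, 2 rose and 30 did not pass; adjusted over the list alone 35 fell and 4 rose. The list's median was -1.03 and camera called it lower (adjusted p = 5.11e-12; adjusted p = 0.406 with an estimated correlation). Besides Col6a1 and Thbs1, the falls included Col6a2, from 63.9 ± 20.4 to 12.6 ± 1.27 CPM (log2 fold change -2.34, SE 0.25, adjusted p = 0.00938), and Col1a1, a chain of the type I collagen of scar tissue, from 298 ± 171 to 30.7 ± 2.92 CPM (-3.28, SE 0.51, adjusted p = 0.0296). P4ha1 and P4ha2, catalytic subunits of the prolyl hydroxylase that modifies collagen, rose instead, by 0.98 (SE 0.11, adjusted p = 0.00938) and 1.25 (SE 0.18, adjusted p = 0.0178). P4ha2 missed the threshold without ECKO replicate 1 (adjusted p = 0.0517) and f/f replicates 2 and 3 (0.0520 and 0.0651), and Col6a2 without ECKO replicate 1 (0.0571). Col1a1 passed without f/f replicate 1 (adjusted p = 1.18e-04) but not without f/f replicates 2 or 3 (0.0629 and 0.0971) or ECKO replicates 1, 2 or 3 (0.106, 0.0961 and 0.0919). Of 30 stellate cell markers 12 fell in the same libraries, with a median of -1.04, and 7 genes stand on both lists. The other 48 matrix genes had a median of -0.71, with 18 lower and 2 higher.

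Of 30 stellate cell and fibroblast markers, 12 fell, none rose and 18 did not pass; adjusted over the list alone 22 fell and 1 rose. Camera called the list lower (adjusted p = 2.64e-09; adjusted p = 0.406 with an estimated correlation). Of the 30, 16 stand on another of the fixed lists. Tcf21 fell as above, Cygb, the globin cytoglobin of stellate cells, fell from 27.3 ± 0.107 to 13.6 ± 1.37 CPM (-1.01, SE 0.12, adjusted p = 0.00938), and Dcn, the collagen-binding proteoglycan decorin, from 705 ± 33.3 to 346 ± 66.6 CPM (-1.03, SE 0.15, adjusted p = 0.0178). Without ECKO replicate 1 the adjusted p was 0.0509 for Cygb and 0.0772 for Dcn, and without f/f replicate 3 it was 0.0779 for Dcn.

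Of 34 genes that TGF-beta commonly induces, 8 fell, 1 rose and 25 did not pass; adjusted over the list alone 11 fell and 2 rose. The median was -0.45 and camera called the list lower (adjusted p = 2.55e-04; adjusted p = 0.406 with an estimated correlation). Thbs1 fell as above, and Fn1, fibronectin, fell from 245 ± 73.4 to 44.1 ± 13.5 CPM (-2.47, SE 0.31, adjusted p = 0.0141). Pdgfb, a growth factor for stellate cells and pericytes, rose from 17.9 ± 1.91 to 32.4 ± 0.662 CPM (0.86, SE 0.12, adjusted p = 0.0141). Without ECKO replicate 1 the adjusted p was 0.0686 for both Fn1 and Pdgfb, and Pdgfb also missed the threshold without ECKO replicate 3 (0.0576) and f/f replicate 3 (0.0557). Of the 34 genes, 7 are on the matrix list and 2 on the stellate list, of whose members 23 of 55 and 12 of 30 fell in the same libraries.

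Of 32 components of the TGF-beta and BMP pathways, 3 rose, none fell and 29 did not pass; adjusted over the list alone 6 rose and 4 fell. The median was 0.01, the mean -0.07 and the camera test pointed up (adjusted p = 0.611). Ltbp4, a latent TGF-beta binding protein, rose from 1356 ± 125 to 2064 ± 62.4 CPM (0.61, SE 0.11, adjusted p = 0.0314). Bmp6, an LSEC-derived inducer of hepatocyte hepcidin, rose by 0.46 (SE 0.09, adjusted p = 0.0396), and Smad6, an inhibitor of BMP signalling, by 0.54 (SE 0.12, adjusted p = 0.0476). Smad6 did not pass without any 1 of the 6 libraries (adjusted p 0.0592 to 0.140). Ltbp4 and Bmp6 passed without f/f replicate 1 (0.0259 and 0.0301), while without each other library their adjusted p was 0.0719 to 0.115 and 0.0639 to 0.172. Of 13 tested BMP-SMAD targets, Smad6 rose, Cd34 and Tmem100 fell and 10 did not pass, with the same counts of 1 and 2 adjusted over the list alone (median -0.16, camera adjusted p = 0.445).

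Of 40 sinusoidal identity genes, 1 rose and 39 did not pass, and none passed adjusted over the list alone. The median was 0.18, turning to -0.05 under total count scaling and on FPKM, and camera called the list higher (adjusted p = 4.06e-04; adjusted p = 0.452 with an estimated correlation); under quantile normalization it pointed down (adjusted p = 0.730). The gene that rose was Clec1b, a C-type lectin receptor, from 180 ± 17.8 to 272 ± 29.8 CPM (0.60, SE 0.12, adjusted p = 0.0414). It passed without f/f replicate 1 (adjusted p = 0.0402) and not without any other single library (0.0556 to 0.154). Oit3 went from 2089 ± 22.2 to 2734 ± 205 CPM (adjusted p = 0.0850) and the scavenger receptor gene Cd36 from 1163 ± 74.2 to 744 ± 137 CPM (adjusted p = 0.0582). In the same libraries the mitochondrial share was 25.3% against 16.4% in f/f (exact permutation p = 0.2), and 12 of 30 stellate markers fell.

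Of 35 genes of capillarized and continuous endothelium, 3 fell, 2 rose and 30 did not pass; adjusted over the list alone 8 fell and 5 rose. The median was 0.06, the mean -0.06 and the test pointed down (adjusted p = 0.970). Cd34, a marker of continuous endothelium that is also on the stellate list, fell from 87.1 ± 16.9 to 38.6 ± 10.3 CPM (-1.17, SE 0.22, adjusted p = 0.0345), and Lamb1, a laminin chain, by 1.32 on the log2 scale (SE 0.18, adjusted p = 0.0153). Selp, the leukocyte adhesion molecule P-selectin, rose from 53.0 ± 11.3 to 107 ± 18.1 CPM (1.01, SE 0.18, adjusted p = 0.0314) and Pecam1, an endothelial junction molecule, from 1133 ± 47.2 to 1615 ± 141 CPM (0.51, SE 0.11, adjusted p = 0.0456). Pecam1 did not pass without any 1 of the 6 libraries (0.0554 to 0.164). Cd34 passed without f/f replicate 1 and ECKO replicate 2 only (0.0159 and 0.0322; otherwise 0.0821 to 0.121), Lamb1 missed without ECKO replicate 1 (0.0775) and f/f replicate 3 (0.0651), and Selp missed without each ECKO replicate (0.0609 to 0.0975) and without f/f replicate 2 (0.0888).

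Of 29 genes of endothelial-to-mesenchymal transition, 6 fell, none rose and 23 did not pass; adjusted over the list alone 14 fell and 1 rose. The median was -0.69 (camera adjusted p = 2.27e-06; adjusted p = 0.406 with an estimated correlation), and 9 of the 29 are also on the stellate list. Cdh11, a mesenchymal cadherin, fell by 2.48 on the log2 scale (SE 0.33, adjusted p = 0.0140) and Mmp2, a matrix metalloproteinase, from 50.1 ± 23.1 to 5.50 ± 0.706 CPM (-3.19, SE 0.40, adjusted p = 0.0153). Without ECKO replicate 1 the adjusted p was 0.0626 for Cdh11 and 0.0775 for Mmp2, and Mmp2 also missed without ECKO replicates 2 and 3 (0.0730 and 0.0702).

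Among 31 angiocrine and vascular tone factors, Pdgfb and Bmp6 rose, Cxcl12 fell and 28 did not pass; adjusted over the list alone 2 rose and 4 fell (median -0.16, camera adjusted p = 0.610). Cxcl12, a chemokine for CXCR4-bearing cells, fell by 1.02 on the log2 scale (SE 0.19, adjusted p = 0.0329). It missed the threshold without ECKO replicates 1 and 3 (0.0990 and 0.0717) and f/f replicates 2 and 3 (0.0686 and 0.115). Of 19 Notch genes, Lfng, a glycosyltransferase that modifies Notch receptors, rose from 38.1 ± 11.9 to 107 ± 21.9 CPM (1.49, SE 0.26, adjusted p = 0.0312), while Notch2 and Maml3 fell and 16 did not pass; adjusted over the list alone 3 rose and 4 fell (median -0.09, camera adjusted p = 0.611). Lfng missed without each ECKO replicate (0.0642 to 0.103) and without f/f replicate 3 (0.111).

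Of 32 adhesion, chemokine and NF-kB genes, Selp rose and 31 did not pass; adjusted over the list alone 1 rose and 4 fell. The median was -0.70 and camera called the list lower (adjusted p = 0.00112; adjusted p = 0.505 with an estimated correlation), a call lost without f/f replicate 1 (adjusted p = 0.0948). Cxcl2, a neutrophil chemokine, went from 19.2 ± 12.9 to 3.13 ± 1.56 CPM (adjusted p = 0.0678). Immediate early genes, a sign of handling, had a median of -0.43 in the same libraries (camera adjusted p = 0.00182; adjusted p = 0.623 with an estimated correlation), and that call too was lost without f/f replicate 1 (adjusted p = 0.0573). Of 14 monocyte markers, only Fn1 passed, and 8 fell adjusted over the list alone (median -1.28, camera adjusted p = 1.01e-04; adjusted p = 0.452 with an estimated correlation). Of 16 neutrophil markers listed, the filter on low counts left 5. Of these Mpo, myeloperoxidase, fell by 3.29 on the log2 scale (SE 0.61, adjusted p = 0.0374). Adjusted over the list alone 3 of the 5 fell (median -1.89, camera adjusted p = 0.00694, or 0.406 with an estimated correlation). Mpo passed without f/f replicate 1 (0.0418) and not without any other library (0.0589 to 0.128).

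Of 21 antigen presentation genes, 6 fell and 15 did not pass; adjusted over the list alone 8 fell and 1 rose. The median was 0.07, the mean -0.65 and the test pointed down (adjusted p = 0.125). The 6 belong to the MHC class II pathway and included H2-Aa, an MHC class II alpha chain, from 18.2 ± 2.23 to 5.54 ± 1.29 CPM (-1.72, SE 0.20, adjusted p = 0.00938), and Cd74, the invariant chain, from 54.3 ± 13.1 to 17.7 ± 4.08 CPM (-1.62, SE 0.22, adjusted p = 0.0153). H2-Aa passed without each library in turn, and Cd74 missed without ECKO replicates 2 and 3 (0.0594 and 0.0668) and f/f replicate 3 (0.0578). Of 16 markers of B and plasma cells, of which B cells carry MHC class II, 4 fell in the same libraries and 15 did so adjusted over the list alone, where 1 rose (median -1.97, camera adjusted p = 7.38e-07; adjusted p = 0.406 with an estimated correlation). Cd79a, part of the B cell receptor, fell from 4.24 ± 1.76 to 0.771 ± 0.316 CPM (-2.45, SE 0.47, adjusted p = 0.0358). It missed the threshold without any library but f/f replicate 1 (0.0806 to 0.126). Xbp1, a transcription factor of plasma cells that also acts in the unfolded protein response of many cells, rose by 0.75 (SE 0.11, adjusted p = 0.0159), and missed without ECKO replicates 1 and 3 (0.0571 and 0.0602) and f/f replicate 3 (0.0731).

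Of 9 dendritic cell markers Clec9a rose by 0.75 (SE 0.13, adjusted p = 0.0307) and 8 did not pass, while adjusted over the list alone 1 rose and 3 fell (median -0.18, camera adjusted p = 0.288). None of 20 Kupffer cell markers (median -0.21, camera adjusted p = 0.738) or 5 T and NK cell markers (median -0.54, camera adjusted p = 0.0754) passed, over all genes or adjusted over the list alone. The filter on low counts left only 5 of the 25 T and NK markers listed, so most of that list was not tested. Without each library in turn the Kupffer median went from -0.48 without f/f replicate 1 to 0.21 without f/f replicate 2, and the T and NK median from -1.05 without ECKO replicate 1 to -0.06 without f/f replicate 2. At an unadjusted p under 0.05 edgeR held 6 Kupffer and 1 T and NK genes, and after adjustment DESeq2 called 1 Kupffer gene higher and 3 lower and 1 T and NK gene lower, and limma-voom 0. Clec4f, a Kupffer cell lectin, had a log2 fold change of 1.26 (SE 0.32, adjusted p = 0.0711). Of 15 cholangiocyte markers 3 fell, and 13 did so adjusted over the list alone (median -1.18, camera adjusted p = 3.48e-07; adjusted p = 0.452 with an estimated correlation), the median being -0.74 without f/f replicate 2. Krt8, a keratin that hepatocytes also express, fell by 1.09 on the log2 scale (SE 0.14, adjusted p = 0.0121), and missed without ECKO replicate 1 (0.0686) and f/f replicate 3 (0.0545). Clec9a passed without f/f replicate 1 and ECKO replicate 2 (0.0179 and 0.0454) and otherwise had an adjusted p of 0.0775 to 0.115.

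Of 12 mesothelial and lymphatic markers 3 fell, and 7 did so adjusted over the list alone (median -1.30, camera adjusted p = 6.06e-05; adjusted p = 0.406 with an estimated correlation), the median being -2.07 without ECKO replicate 2. Lrrn4, a mesothelial gene, fell by 2.56 on the log2 scale (SE 0.48, adjusted p = 0.0337), and passed without f/f replicate 1 only (0.0232; otherwise 0.0594 to 0.114). Of 9 erythroid and platelet markers Alas2, the erythroid enzyme that begins heme synthesis, rose from 1.83 ± 0.507 to 8.60 ± 1.70 CPM (2.22, SE 0.28, adjusted p = 0.0108), against the direction of the list. Adjusted over the list alone 5 members fell and 1 rose (median -1.04, camera adjusted p = 0.0124; adjusted p = 0.428 with an estimated correlation). That list's call was lost under total count scaling (adjusted p = 0.105) and with a mean of at least 1 CPM (0.0818), its median was -0.67 without ECKO replicate 3, and Alas2 missed without ECKO replicate 1 (0.0592).

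None of 40 cell cycle genes passed over all genes, while adjusted over the list alone 17 fell. At an unadjusted p under 0.05 edgeR held 27, all lower, while after adjustment DESeq2 called 16 lower and limma-voom 0. The median was -1.05 and camera called the list lower (adjusted p = 4.39e-07; adjusted p = 0.539 with an estimated correlation). Mki67, the proliferation marker Ki-67, went from 39.3 ± 19.4 to 11.6 ± 2.83 CPM (adjusted p = 0.0776), and Mcm2, a replication helicase subunit, from 30.8 ± 2.31 to 22.9 ± 0.567 CPM (adjusted p = 0.0651). Within f/f, Mki67 was at 16.9 CPM in replicate 1 and 51.0 CPM in replicate 2 (404, 1039 and 1207 counts in replicates 1 to 3), against 9.35 to 14.8 CPM in the libraries labelled ECKO. The stellate, monocyte and B cell markers given above, with medians of -1.04, -1.28 and -1.97, differed between the same libraries. Of 41 interferon response genes Oas2, an antiviral oligoadenylate synthetase, fell by 1.05 on the log2 scale (SE 0.19, adjusted p = 0.0307) and 40 did not pass; adjusted over the list alone 1 fell. The median was 3e-04, the mean -0.15 and the test pointed up (adjusted p = 0.687). Oas2 passed without f/f replicate 1 only (0.0324; otherwise 0.0518 to 0.115), and without f/f replicate 1 camera called the interferon list higher (adjusted p = 0.00327; adjusted p = 0.690 with an estimated correlation).

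Of 27 hypoxia and glycolysis genes P4ha1 rose, Slc2a1, the glucose transporter GLUT1, fell by 0.82 on the log2 scale (SE 0.13, adjusted p = 0.0241) and 25 did not pass; adjusted over the list alone 4 rose and 1 fell (median -0.04, camera adjusted p = 0.970). Slc2a1 passed without f/f replicate 1 only (0.0246; otherwise 0.0512 to 0.110). None of 34 nuclear genes of oxidative phosphorylation passed in edgeR, over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Their median was 0.18, turning to -0.06 under total count scaling and on FPKM and being 0.11 without ECKO replicate 2, and camera called the list higher (adjusted p = 4.06e-04; adjusted p = 0.550 with an estimated correlation). Ndufa1, a subunit of complex I, went from 13.7 ± 1.68 to 20.2 ± 3.29 CPM (adjusted p = 0.0981). The mitochondrial genome transcripts had a median of 0.91 in the same libraries, with 0 of 13 passing, as given above. Cytosolic ribosomal protein genes had a median of -0.05, with 0 of 49 passing over all genes or adjusted over the list alone (camera adjusted p = 0.378), 5 at an unadjusted p under 0.05 in edgeR and 0 called by DESeq2 or limma-voom.

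Of 35 lipid uptake and metabolism genes 3 fell and 32 did not pass; adjusted over the list alone 13 fell and 2 rose. The median was -0.16 (camera adjusted p = 0.0254; adjusted p = 0.406 with an estimated correlation), being -0.25 without f/f replicate 2, and the call was lost with no filter on low counts (adjusted p = 0.0794). Lrp1, an endocytic lipoprotein receptor, fell from 124 ± 9.52 to 47.8 ± 6.19 CPM (-1.37, SE 0.12, adjusted p = 0.00853). Of 32 endocytosis and scavenging genes, Lrp1 and Cd63 fell, Scarb2 rose and 29 did not pass; adjusted over the list alone 4 fell and 2 rose. The median was 0.06, the mean -0.09 and the test pointed up (adjusted p = 0.754). Cd63, a tetraspanin of late endosomes, fell from 47.2 ± 5.29 to 16.8 ± 1.69 CPM (-1.49, SE 0.13, adjusted p = 0.00853), and Scarb2, a lysosomal membrane protein, rose from 535 ± 24.3 to 833 ± 34.7 CPM (0.64, SE 0.09, adjusted p = 0.0178). Lrp1 and Cd63 passed without each library in turn. Scarb2 missed without ECKO replicates 1 and 3 (0.0772 and 0.0707) and f/f replicate 3 (0.105).

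Of 30 hepatocyte markers Mup20 rose, Cyp3a11 fell and 28 did not pass; adjusted over the list alone 2 rose and 1 fell. The median was 0.44 and camera did not call the list in the main test (adjusted p = 0.122). Without f/f replicate 1 camera called it higher (adjusted p = 4.18e-04, or 0.690 with an estimated correlation). That median was 0.90 without f/f replicate 1 and 0.11 without ECKO replicate 2. Mup20, a major urinary protein, rose from 11.2 ± 2.18 to 54.4 ± 20.8 CPM (2.28, SE 0.30, adjusted p = 0.0153), and Cyp3a11, a drug-metabolizing cytochrome P450, fell from 13.4 ± 0.895 to 2.43 ± 1.11 CPM (-2.45, SE 0.29, adjusted p = 0.00963). Without ECKO replicate 1 the adjusted p was 0.0646 for Mup20 and 0.0589 for Cyp3a11, and without f/f replicate 3 it was 0.0621 for Mup20. Of 32 immediate early genes Egr2, Nr4a1 and Cyr61 fell and 29 did not pass; adjusted over the list alone 8 fell and 1 rose. Their median was -0.43 (camera adjusted p = 0.00182; adjusted p = 0.623 with an estimated correlation), being -0.73 without f/f replicate 2, and the call was lost without f/f replicate 1 (adjusted p = 0.0573). Egr2 fell from 4.37 ± 1.00 to 0.693 ± 0.153 CPM (-2.65, SE 0.32, adjusted p = 0.00963), with an adjusted p of 0.0509 without ECKO replicate 1.

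Medians of other lists that camera did not call also moved with single libraries. Without each library in turn they were -0.01 to 0.07 for TGF-beta and BMP pathway components, -0.42 to -0.09 for BMP-SMAD targets, -0.01 to 0.15 for capillarized endothelium, -0.23 to -0.03 for angiocrine factors and -0.19 to 0.01 for Notch genes. They were -0.21 to 0.21 for interferon response, -0.15 to 0.28 for antigen presentation, -0.11 to 0.03 for hypoxia and glycolysis, 0.03 to 0.09 for endocytosis, -0.79 to -0.08 for dendritic cell markers and -0.17 to 0.03 for ribosomal protein genes.

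**Figure D3:**
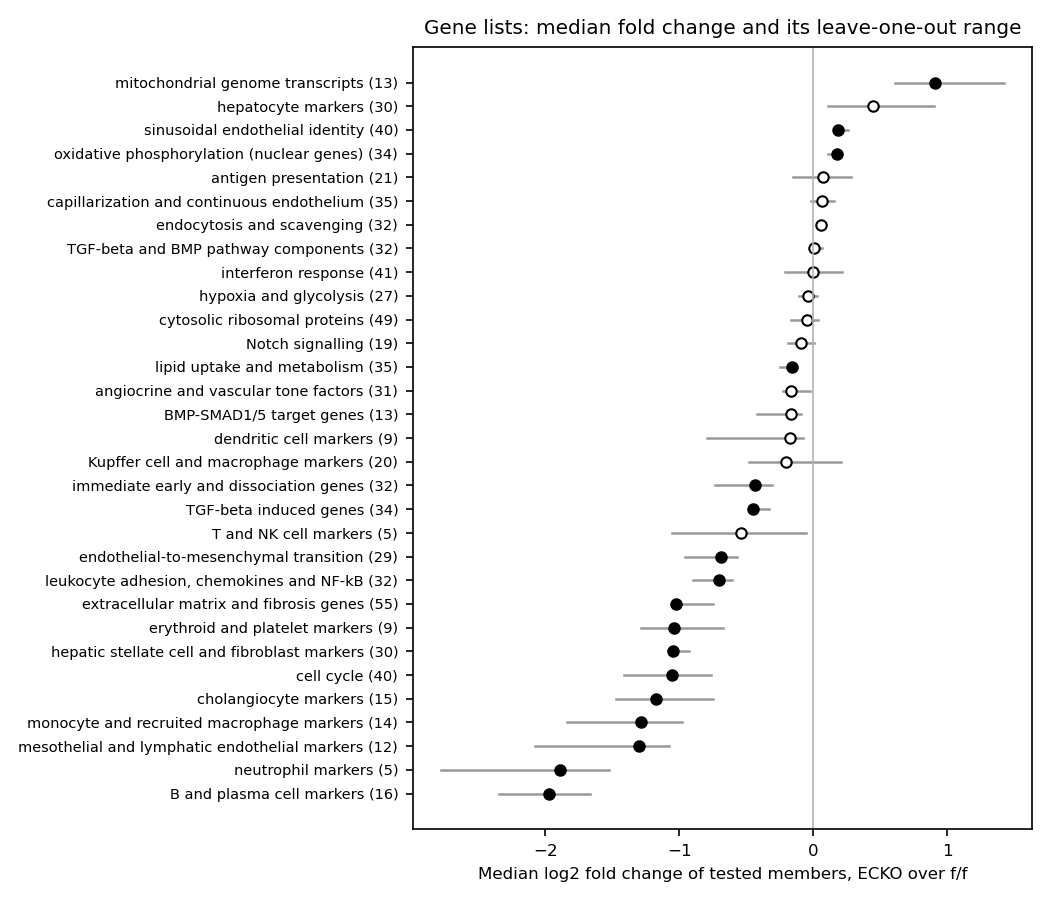
Median log2 fold change (libraries labelled ECKO over f/f) of the 31 gene lists, with the number of tested members in parentheses; filled dots have a camera adjusted p under 0.05 with the preset correlation and lines span the medians without each library in turn. Of the lists, 14 lie lower and 3 higher by that test, 0 with an estimated correlation, and the small positive medians of sinusoidal identity and oxidative phosphorylation turn to -0.05 and -0.06 under total count scaling and on FPKM.

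Several of the largest rises among named genes were in genes of the male mouse liver. Mup14 rose from 0.174 ± 0.0674 to 24.0 ± 6.38 CPM (7.05, SE 0.34, adjusted p = 2.63e-04). Mup15 had 0 counts in f/f and 116 in the libraries labelled ECKO, at least 53.3-fold higher against a floor of 3 counts over the f/f group. Hsd3b5, a male-specific hydroxysteroid dehydrogenase, had 1 count against 143 (ratio 197, counting interval 34.8 to 7833), Mup17 had 2 against 198 (ratio 136, interval 37.2 to 1134), and Elovl3, a fatty acid elongase, 1 against 110 (ratio 151, interval 26.6 to 6038). The remaining rises named by size were Mup11, Mup21, Mup7, Cyp4a12a, Mup16, Selenbp2 and Serpina12, with log2 fold changes of 6.59 to 3.81. The f/f counts of Mup11 (5), Mup16 (4) and Mup17 (2) were all in f/f replicate 1, which also held 81 counts of Mup7 against 2 and 15 in the other f/f libraries. Without it the log2 fold changes of these genes were 10.2, 8.27, 9.24 and 7.41 in place of 6.59, 4.98, 6.82 and 5.53. Without f/f replicate 2, which held the single f/f counts of Hsd3b5 and Elovl3, theirs were 8.83 and 8.44 in place of 7.11 and 6.73, and that of Mup21 was 6.61 in place of 5.63. Where no count is left in f/f these are fitted values that depend on the prior count. The Mup values are uncertain because paralogs can share reads. Mup14, Mup17 and Selenbp2 passed without each library in turn. The others lost their call without ECKO replicate 1 (adjusted p 0.0509 to 0.0957), Serpina12, Mup7 and Mup16 also without f/f replicate 3 (0.0651, 0.105 and 0.101), Mup7 and Mup16 also without ECKO replicates 2 (0.0717 and 0.0756) and 3 (0.0668 for both), and Mup16 also without f/f replicate 2 (0.0562).

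Among the largest falls, Saa3, an acute phase serum amyloid gene, went from 35.4 ± 18.7 to 1.45 ± 0.335 CPM (-4.59, SE 0.45, adjusted p = 0.00938). Serpinb2, the protease inhibitor PAI-2, had 289 counts in f/f and 1 in the libraries labelled ECKO (ratio 210, counting interval 37.4 to 8317; adjusted p = 0.0241). Ltbp2, a matrix protein related to the latent TGF-beta binding proteins, fell from 21.3 ± 14.2 to 0.877 ± 0.256 CPM (-4.58, SE 0.77, adjusted p = 0.0318). Fhl2, Chil1, Col6a5, Aldh1a2, Csdc2, Pcnxl2, Svep1, Mpo and Col1a1 completed the 12, with log2 fold changes of -5.26 to -3.28. Chil1 had 5 counts in the libraries labelled ECKO, all in ECKO replicate 2, and without it its log2 fold change was -8.82 in place of -4.73, and that of Fhl2 -6.78 in place of -5.26. Without ECKO replicate 3, which held its single count, that of Serpinb2 was -9.47 in place of -7.38. Saa3 missed the threshold without ECKO replicate 1 (0.0509), Serpinb2 without each ECKO replicate (0.0855 to 0.105), and Ltbp2 without any library but f/f replicate 1 (0.0678 to 0.111). Over all 79 named genes that passed, 10 passed without each library in turn, and 68 no longer did without ECKO replicate 1, 51 without f/f replicate 3, 46 without ECKO replicate 3, 38 without ECKO replicate 2, 33 without f/f replicate 2 and 3 without f/f replicate 1.

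Calls of genes with small rises also depended on the scaling. Under total count scaling the calls of Ltbp4 (0.37, adjusted p = 0.173), Bmp6 (0.22, 0.371), Smad6 (0.31, 0.306), Clec1b (0.36, 0.175), Pecam1 (0.28, 0.378) and Scarb2 (0.40, 0.157) ended. So did those of Pdgfb (0.61, adjusted p = 0.0682), Selp (0.77, 0.0883), Lfng (1.23, 0.0663), Xbp1 (0.52, 0.0829) and Clec9a (0.51, 0.0768). The FPKM test (limma-trend) ended the same 11 calls and those of P4ha1 (0.71, adjusted p = 0.0655), P4ha2 (0.82, 0.0610), Col1a1 (-3.01, 0.0558) and Lpl, lipoprotein lipase (-1.08, 0.0759). With no filter on low counts the calls of Col1a1, Col1a2, Ltbp2, Mpo and Mup7 ended (adjusted p 0.0792, 0.0532, 0.0812, 0.0664 and 0.0741), and with size factors from DESeq2 or without mitochondrial genes that of Smad6 (0.0510 and 0.0503). With limma-voom the calls that ended included Ltbp2, Serpinb2, Mpo, Cd79a and Lrrn4 (0.175, 0.0604, 0.0517, 0.0835 and 0.0586). The falls of Col6a1, Thbs1, Tcf21, H2-Aa, Lrp1 and Cd63 passed in each of these.

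The smallest p of the comparison belonged to Rab22a (ENSMUSG00000027519, chromosome 2, 173659760 to 173707343 on mm10/GRCm38, plus strand), which encodes an endosomal small GTPase and was chosen after its values were seen. It rose from 16.4 ± 0.639 to 86.7 ± 4.26 CPM (2.40, SE 0.10, adjusted p = 1.37e-04), and passed without each library in turn, with log2 fold changes of 2.37 to 2.45. On FPKM its change was 1.56 on the log2(FPKM + 1) scale, which understates changes of genes with low values.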

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

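The tests of total count scaling, 1 CPM and the block, or 1 library fewer, with an estimated correlation for the lists, of FPKM, and without mitochondrial or other-cell-type genes were chosen after seeing the data. Under size factors from DESeq2 (152 higher, 402 lower), no filter on low counts (223, 505), a mean of at least 1 CPM (150, 363), no mitochondrial genes (163, 378) and no genes of the other-cell-type lists (160, 360) both counts stayed within 1.5 times of 170 and 382, and none of the 552 calls reversed in any setting. Total count scaling gave 63 higher and 1209 lower, 770 of them lower by at least 1 on the log2 scale. The DESeq2 Wald test gave 451 and 1033, of which 104 and 735 changed by at least 1. It also called more unchanged genes in the simulated data (23.8% of its calls). Limma-voom gave 200 lower, 148 by at least 1. The FPKM test gave 28 higher, with 17 higher and 132 lower by at least 1. The log2 fold change of Tgfbr2 turned to -0.0248 under total count scaling and -0.0105 on FPKM. For these the cause was not tested, except that total count and FPKM scaling share 1 construction, division by the library total, with medians of all tested genes of -0.22 and -0.15 (the latter over 10464 genes) against 0.01 in the main test. Without each library in turn, with fewer samples, 14 to 246 genes were higher and 21 to 766 lower, and 13 to 99 and 21 to 632 by at least 1, while the change of Tgfbr2 was 0.17 to 0.28. Of 136 named genes, 135 kept 1 direction in all settings, the exception being Tgfbr2. Camera called 14 lists lower and 3 higher, and with an estimated correlation 0 and 0 (3 lower and 0 higher at an unadjusted p under 0.05). With fry 5 and 0 passed, under quantile normalization 1 was higher, and without each library in turn 3 to 5 were higher. The 5 by fry were the TGF-beta induced, matrix, endothelial-to-mesenchymal transition, lipid and stellate lists (fry adjusted p 0.0308 to 0.0448). Fry's mixed test asks whether a list's genes change in any direction, without comparing them with other genes. Lists it passed without a camera call included TGF-beta and BMP components, Notch (adjusted p = 0.00124 for both) and hypoxia (7.18e-05). It did not pass interferon response, ribosomal protein (0.399 for both), hepatocyte (0.0632), Kupffer (0.0858) or T and NK genes (0.114). For these changes of list calls the cause was not tested. The first principal component held 50.1% of variance over all tested genes. The replicate numbers do not pair the libraries by the labels; same-numbered libraries deviated together with correlations of 0.0946, 0.152 and -0.0520, so not every library correlated best with its own number. With the replicate block edgeR called 131 higher and 285 lower, 321 of them among the 552, the block kept all 17 list calls, and with an estimated correlation and the block, or without f/f replicate 1, 0 and 0 lists passed. The limma-trend test planned for a table of only normalized values was run here as the FPKM test. Alternatives to it planned for such a table were not run because the table holds counts. Depth limits genes near the floor, such as Mup15 with 0 counts in f/f.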

Other observations

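The lists of this part were written after some of their members had been seen, and the tests of sex-biased genes, hepatocyte RNA, female mice, Mup paralogs and the dependence of the matrix list on a single library were chosen only after the result was seen. Of 22 genes of protein entry, folding, quality control and stress signalling in the endoplasmic reticulum, 7 rose and none fell in the libraries labelled ECKO. Besides chaperones the 22 include the transcription factors Xbp1, which rose, Atf4 (-0.30, adjusted p = 0.447) and Ddit3 (-0.15, adjusted p = 0.647). The median log2 fold change of the 22 was 0.49 (camera adjusted p = 6.28e-08, or 0.171 with an estimated correlation). Over the 20 members not seen beforehand the median was 0.45 with 5 higher. Creld2, a secreted stress-induced protein, rose from 32.1 ± 6.33 to 87.9 ± 12.1 CPM (1.45, SE 0.17, adjusted p = 0.00958) and passed without each library in turn. Hyou1, a chaperone, rose by 0.78 (SE 0.10, adjusted p = 0.0117), but missed the threshold without ECKO replicates 1 and 3 (0.0592 and 0.0502), under total count scaling (0.53, adjusted p = 0.0531) and on FPKM (0.50, 0.0956). Hspa5, the chaperone BiP, had a log2 fold change of 0.50 (SE 0.31, adjusted p = 0.366). Under total count scaling the median of the list was 0.24 with 1 of 22 higher, and on FPKM 0.21 with 1 higher. In the same libraries the mitochondrial share was 25.3% against 16.4% in f/f, and hepatocyte genes without sex bias had a median of 0.39 (camera adjusted p = 0.0251; adjusted p = 0.613 with an estimated correlation).

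Of 6 clock genes that peak with Arntl, Arntl itself rose from 4.31 ± 0.880 to 11.4 ± 1.78 CPM (1.40, SE 0.21, adjusted p = 0.0184), with a list median of -0.28 (-0.05 without ECKO replicate 2 and -0.42 without ECKO replicate 3; camera adjusted p = 0.593). Of 10 that peak opposite to it Nr1d1 rose by 0.86 (SE 0.16, adjusted p = 0.0327), with a list median of 0.16 (0.27 without f/f replicate 1) that turned to -0.08 under total count scaling and -0.27 on FPKM (camera adjusted p = 0.212). Arntl missed the threshold without ECKO replicates 1, 2 and 3 and f/f replicate 3 (0.0704, 0.0512, 0.0605 and 0.0811). Nr1d1 passed without f/f replicate 1 only (0.0366; otherwise 0.0594 to 0.107), and missed under total count scaling (0.0997) and on FPKM (0.169).

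Of 55 matrix genes 23 fell and 2 rose in the libraries labelled ECKO (list adjusted p = 0.406 with an estimated correlation). The median of the matrix list nearest 0 without a single library was -0.75, so no library alone accounts for the fall. Single calls were often lost in these fits with fewer samples. Col1a1 passed in 1 of 6 such fits, while its log2 fold change stayed at -3.68 to -2.92. A call lost in that way is not tied to a given library. Less RNA from stellate cells may account for some of it. In the same libraries 25 stellate markers that are not matrix genes had a median of -0.75 (7 lower, leave-one-out medians -0.84 to -0.56). Camera called them lower (adjusted p = 9.02e-07, or 0.321 with an estimated correlation). Their median lay below all 10000 random lists matched on expression, but those lists were drawn gene by gene and lack the markers' shared movement. Of the 25, 18 are on a fixed list, and 17 are on the stellate list that fell above. Among them Hgf (0.12), Ecm1 (0.23) and Hhip (0.97) did not fall. The sort or gate is not given in the sources used here. Lower transcription in the endothelial cells cannot be told apart from less stellate cell RNA. The 16 basement membrane genes that endothelium makes had a median of -0.23 (5 lower, leave-one-out medians -0.32 to -0.15, camera adjusted p = 0.00637; adjusted p = 0.257 with an estimated correlation), below all 10000 matched random lists, but 15 of the 16 are on the matrix list itself and stellate cells make some of them too, so their fall decides nothing. The stellate markers do not separate fewer stellate cells in the preparation from fewer or quieter ones in the liver.

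Of 32 male-biased liver genes 17 were higher in the libraries labelled ECKO, with a median of 2.12, the same with genes at 0 counts set to their bound (camera adjusted p = 2.70e-19; adjusted p = 0.171 with an estimated correlation), while 18 female-biased genes had a median of -1.07 with 3 lower (camera adjusted p = 4.91e-04; adjusted p = 0.173 with an estimated correlation; -0.09 on FPKM). More hepatocyte RNA alone would have moved other hepatocyte genes alike, but 40 hepatocyte genes without sex bias had a median of 0.39 (0.14 to 0.80 without each library; camera adjusted p = 0.0251, adjusted p = 0.613 with an estimated correlation). Female f/f mice are excluded by Y-linked Ddx3y, at 786 counts or more in all 6 libraries, with Xist at 0 to 2. Shared Mup reads alone would not raise the 9 of 21 male-biased genes not named Mup that were higher. The median of the 21 was 1.43, but it cannot decide the question for the list, as it includes members already seen. All 9 were among members already seen; the 12 not seen beforehand had a median of 0.60 (0.52 to 1.37 without each library in turn) with none higher, and 0.60 lies within the 0.14 to 0.80 of the hepatocyte genes without sex bias. A hypothesis that rests largely on members already seen is a more male-typical programme in the hepatocytes whose RNA reached these libraries, as the male-biased minus female-biased median over members not seen beforehand was 1.498 (1.63 to 2.42 without each library in turn, all above it), with 1 of 16 higher and 2 of 17 lower. Aox3 and Cyp4a14 were chosen after their values were seen, so they are examples and add no support to that hypothesis. Aox3, among the 9 above, rose by 2.32 (SE 0.27, adjusted p = 0.00938) and passed without each library in turn. Cyp4a14 fell by 3.17 (SE 0.45, adjusted p = 0.0153), from 2.05 ± 0.330 to 0.221 ± 0.118 CPM, close to the floor for a count of 0. It missed the threshold without ECKO replicates 1 and 3 (0.0801 and 0.0637) and f/f replicate 3 (0.0651).

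Rab22a rose by 2.40 on the log2 scale. A chromosomal change near it carried with the engineered alleles cannot be told apart from a response to genotype, as 0 of 15 other tested genes within 1 Mb passed, while 2 neighbours that separated the groups changed by more than 0.58 on the log2 scale, Bmp7 (-0.71, adjusted p = 0.264) and Ppp4r1l-ps (-0.60, adjusted p = 0.136). Of the 15, 5 separated the groups, 3 lower and 2 higher, against 30.9% of all genes. The latter ends at 173659640 on chromosome 2 (mm10/GRCm38), just before Rab22a starts at 173659760.

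Of 195 tested genes within 10 Mb of Tgfbr2, 9 (4.62%) passed, against 4.02% elsewhere (one-sided Fisher exact p = 0.388). The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05; the real split called 552 genes and the highest of the others 1.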
